A study of Homo sapiens with 60 samples.

How the data were processed

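HT29, an established human colorectal adenocarcinoma cell line, was treated for 24 h with 1 of 6 herbal water extracts at 500, 100 or 20 µg/mL, with the phosphoinositide 3-kinase (PI3K) inhibitors wortmannin or LY294002 at 10 µM, or with vehicle. The extracts came from Poria cocos (below: Poria), Atractylodis Rhizoma (Atractylodis), Glycyrrhizae Radix, which is licorice root (Glycyrrhizae), Panax ginseng (Ginseng), Angelicae Gigantis Radix (Angelicae) and Paeoniae Radix (Paeoniae). Per the labels, the vehicle was 0.1% DMSO, while the series text gives 2% DMSO. The series text also says that an extract with an IC20 under 500 µg/mL was used at lower doses, but the labels of all libraries used here give 500, 100 and 20 µg/mL. Which library carried which treatment was taken from the sample labels.

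Per the labels, 1 µg of total RNA with a RIN over 7 went into an MGI directional mRNA library and was read as 100 bp pairs. The authors checked reads with FastQC 0.11.9, trimmed them with Trim Galore 0.6.5, aligned them to GRCh38 (hg38) with STAR 2.7.3a and quantified genes with RSEM 1.3.3. The deposited table holds RSEM expected counts per Ensembl gene, not normalised, and 24.2% of the values above 0 were not whole numbers. The authors' gene annotation release and strand setting are not given in the sources used here. The table has 273 columns, of which 60 belong to these libraries and 213 were not used here. It has 60675 genes, 26276 of them without a count in the 60 libraries. Symbols and coordinates (GRCh38, GENCODE 29) were joined by Ensembl identifier, which gave a symbol to 41209 genes of the table and 14871 of the 16767 genes tested.

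Expected counts were rounded, and genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 16767 genes. Library composition was normalised by TMM. One negative binomial quasi-likelihood model with a mean for each of 21 groups was fitted to all 60 libraries, with 39 residual degrees of freedom (glmQLFit and glmQLFTest). The plan written before the data were examined gave the number of groups as 20, a miscount with no effect on the model. The common biological coefficient of variation was 0.0570. P-values were adjusted by Benjamini-Hochberg over the genes of each of 30 comparisons, and a gene is said to rise or fall where the adjusted p was under 0.05. Log2 fold changes are given with the standard error (SE) that the quasi-likelihood F statistic implies, and levels as CPM (counts scaled to a common library total with the TMM factors), mean ± SD over the libraries of a group.

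The comparisons were each inhibitor and each extract dose against vehicle, wortmannin against LY294002, 500 against 20 µg/mL of each extract, and the difference of that dose effect between the extracts whose sample codes begin with the same number. The codes begin with 1 for vehicle and inhibitors, 2 for Poria and Atractylodis, 3 for Glycyrrhizae and Ginseng, and 4 for Angelicae and Paeoniae, called code sets below. The meaning of that number is not stated, so each extract-against-vehicle comparison also compares code sets, whereas 500 against 20 µg/mL stays within a set. The labels do not say whether replicates were separate cultures. Correlations between replicates were taken on residuals, which are log2 CPM less the mean of the group. Residuals of the same number correlated above 0.1 in each of 3 pairs in 2 of 27 comparisons of 2 groups, wortmannin with vehicle and Ginseng 500 with 20. The comparisons with Paeoniae, which have 2 pairs, could not meet this rule. Taken over all groups, the mean correlation of residuals was 0.126 for the same number and -0.0627 for different numbers. The second value largely follows from the first, since residuals cancel out within a group. A model with the replicate number as a block was therefore run as an alternative. In 57 pairs of replicates, the median spread was at least 0.718 against 0.455 under counting noise alone, so no pair looked like the same library counted again.

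Lists of genes, 34 in all, were fixed before the data were examined: 29 had at least 5 tested members and were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. Adjustment was over 232 tests against vehicle and 174 tests of 500 against 20 µg/mL. Each list was also tested with an inter-gene correlation estimated from the residuals, which is the stricter test of the pair. A list adjusted p in the Results comes from the preset correlation unless the estimated one is named. The latter is printed there where it was not under 0.05. Marker lists of fibroblasts, leukocytes, endothelium, hepatocytes and lung epithelium had 2, 3, 2, 2 and 0 tested members and no test.

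Genes named in the text were chosen by a rule fixed before the data were examined: genes past the threshold with the largest changes at a mean of at least 5 CPM where all treated libraries lay on one side of all control libraries, the list members with the smallest adjusted p, and a fixed set of reference genes. The rule for the difference of dose effects left out the condition on libraries. Genes named outside it are given as chosen after their values were seen. Some genes that the rule chose are not reported here. Clone names and antisense, microRNA host and other noncoding names were left out of the rule.

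The procedure was tested on simulated counts, drawn from a negative binomial model with the totals and the spread per gene of these libraries. All groups had the same mean profile apart from known changes. Genes were drawn independently, so the list tests on them met no correlation between genes. For 3 against 3 libraries the procedure found 48.0%, 70.0%, 90.0% and 96.0% of genes changed 1.25, 1.5, 2 and 4 times, with 11 of 163 calls false. For Paeoniae, with 2 libraries, the shares were 46.9%, 61.7%, 79.6% and 84.0%, with 5 of 138 calls false. A shift of 0.3 in 1 list was found, and 0 of 404 other list tests passed by camera with either correlation. Random regroupings of the real libraries, which hold real effects, passed far more with the preset correlation, a median of 58 of 232 and 48 of 174 tests, and a median of 0 with an estimated one.

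The alternatives were DESeq2 size factors, no filter on low counts, the replicate block, DESeq2 1.42.0 (Wald test) in place of edgeR, a fit of the compared groups alone, and leaving out each library in turn. Offsets for transcript length and GC content were added after the data were seen, for 16647 genes tested (99.3%) with a length. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3, were used.

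Total counts per library ran from 20431980 to 35477712, so that 1 count was 0.0489 to 0.0282 CPM. Precision statements cover counting and replicate spread only, since no molecular identifiers are described for the reads.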

Results

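Messenger RNA was sequenced from 60 libraries of HT29 cells after 24 h of treatment. The libraries fell into 21 groups: vehicle, 2 inhibitors and 6 extracts at 3 doses each. There were 3 libraries in 18 groups and 2 in each of the 3 Paeoniae groups. The deposited expected counts summed to 20431980 to 35477712 per library. Genes encoded in mitochondria took 9.96 ± 1.38% of the counts in vehicle (SD, n = 3) and between 7.56% and 9.96% in the group means. Marker genes of fibroblasts, endothelium, leukocytes, hepatocytes and lung epithelium had means under 1 CPM over all libraries, apart from LYZ at 1496 CPM, SERPINA1 at 414 CPM, APOH at 21.6 CPM, CD68 at 6.75 CPM, CD14 at 3.59 CPM, PECAM1 at 1.70 CPM and COL1A1 at 1.26 CPM. Genes called here rose or fell at a Benjamini-Hochberg adjusted p under 0.05 among 16767 genes tested. A gene list described without a second p kept an adjusted p under 0.05 with an estimated inter-gene correlation.

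Wortmannin, a covalent PI3K inhibitor used as a positive control, raised genes of the antiviral interferon response and lowered genes of mitosis. OAS2, an antiviral oligoadenylate synthetase (chromosome 12, 112978395 to 113011723), rose from 3.30 ± 0.65 CPM in vehicle to 11.9 ± 3.44 CPM (SD, n = 3 each), a log2 fold change of 1.84 ± 0.21 (SE, adjusted p = 7.59e-09). MX1, a GTPase that blocks influenza and other viruses (chromosome 21, 41420304 to 41459214), rose from 6.35 ± 0.28 to 19.4 ± 3.43 CPM, a log2 fold change of 1.61 ± 0.14 (adjusted p = 9.44e-12). PLK1, a kinase of mitotic entry and spindle assembly (chromosome 16, 23677656 to 23690367), fell from 176 ± 15.3 to 114 ± 9.94 CPM, a log2 fold change of -0.63 ± 0.06 (adjusted p = 3.19e-10). ASNS, which makes asparagine, fell from 53.4 ± 1.27 to 32.8 ± 1.40 CPM, a log2 fold change of -0.70 ± 0.06 (adjusted p = 9.34e-13).

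By list, 28 of 29 interferon-stimulated genes rose with wortmannin (28 adjusted over the list alone), with a median log2 fold change of 0.89 and a list adjusted p of 2.95e-37. Besides MX1 and OAS2, IFIT1 changed by 1.47 ± 0.11 and IFI27 by 1.38 ± 0.18. Of 28 genes of mitosis and G2/M, 27 fell (27 adjusted over the list alone), with a median of -0.44 and a list adjusted p of 4.77e-48. AURKA, a spindle kinase, changed by -0.63 ± 0.04, CDC20, an activator of the anaphase-promoting complex, by -0.58 ± 0.04 and PTTG1, which is securin, by -0.71 ± 0.06. Of 12 aminoacyl-tRNA synthetases, 9 fell (11 adjusted over the list alone), among them YARS1 by -0.47 ± 0.03, with a list adjusted p of 1.79e-11. Genes of the ATF4 amino acid response fell in 9 of 26 cases (10 adjusted over the list alone; list adjusted p = 5.3e-08), and chaperones of the unfolded protein response in 8 of 18 (12 adjusted over the list alone; list adjusted p = 7.63e-11), HSP90B1 by -0.41 ± 0.04. Wnt targets and intestinal stem cell genes rose in 6 of 16 cases (7 adjusted over the list alone; list adjusted p = 0.000221), LGR5, a stem cell receptor, by 0.34 ± 0.07. Among 24 targets of FOXO, the transcription factors that PI3K and AKT keep out of the nucleus, 7 rose and 2 fell (9 and 2 adjusted over the list alone). TXNIP, an inhibitor of glucose uptake, rose by 0.68 ± 0.07 on the log2 scale and INSR, the insulin receptor, by 0.48 ± 0.07, but the FOXO list had an adjusted p of 0.000221 and an adjusted p of 0.121 with an estimated correlation. Wortmannin changed 2300 genes in all, 1050 higher and 1250 lower, of which 80 changed at least 2-fold. Leaving out 1 library gave 1570 to 2186 genes, and a fit of these 6 libraries alone gave 1249. Most called genes were lower here, but most were higher in that fit (704 against 545) and without a filter on low counts (1082 against 948).

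LY294002, a reversible PI3K inhibitor, lowered genes of mitosis and of DNA replication and raised TXNIP. PLK1 fell from 176 ± 15.3 CPM in vehicle to 83.4 ± 5.53 CPM (SD, n = 3 each), a log2 fold change of -1.08 ± 0.07 (SE, adjusted p = 2.5e-18). TXNIP (chromosome 1, 145992435 to 145996600) rose from 51.1 ± 0.892 to 140.3 ± 18.6 CPM, a log2 fold change of 1.46 ± 0.07 (adjusted p = 1.16e-21). DPYSL3, a cytoskeletal protein of neurite growth (chromosome 5, 147390811 to 147510056), rose from 3.16 ± 0.292 to 14.7 ± 1.22 CPM, a log2 fold change of 2.21 ± 0.14 (adjusted p = 6.15e-18). ANXA13, a membrane-binding annexin of intestinal epithelium (chromosome 8, 123680794 to 123737407), fell from 25.8 ± 1.79 to 6.06 ± 0.994 CPM, a log2 fold change of -2.09 ± 0.12 (adjusted p = 6.75e-19).

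By list, all 28 genes of mitosis and G2/M fell with LY294002 (28 adjusted over the list alone), with a median log2 fold change of -0.67 and a list adjusted p of 1.43e-33. All 28 genes of DNA replication and G1/S fell too (28 adjusted over the list alone; median -0.57; list adjusted p = 4.08e-26). AURKA (chromosome 20, 56369389 to 56392337) changed by -0.98 ± 0.04, CCNA2, a cyclin of S phase and G2, by -0.87 ± 0.05, RRM2, a subunit of ribonucleotide reductase, by -0.72 ± 0.03 and CDC45, part of the replicative helicase, by -0.72 ± 0.05. Aminoacyl-tRNA synthetases fell in 11 of 12 cases (11 adjusted over the list alone; list adjusted p = 8.59e-09), genes of ribosome biogenesis in 20 of 25 (24; 5.3e-08) and the ATF4 response in 16 of 26 (17; 7.08e-07). Of 18 heat shock genes 14 fell and 2 rose (14 and 3 adjusted over the list alone; list adjusted p = 1.69e-07), HSPH1 by -0.79 ± 0.04. Targets of PPAR and genes of fatty acid oxidation rose in 9 of 12 cases (10 adjusted over the list alone; list adjusted p = 0.000153). FOXO targets rose in 15 of 24 cases and fell in 2 (15 and 2 adjusted over the list alone), with a median of 0.32, and the list had an adjusted p of 1.35e-05 and an adjusted p of 0.0677 with an estimated correlation. IRS2, an adaptor of the insulin receptor, changed by 0.60 ± 0.08 and YPEL3 by 0.86 ± 0.11. Cytosolic ribosomal proteins rose in 45 of 74 cases (47 adjusted over the list alone), with a list adjusted p of 8.73e-08 and an adjusted p of 0.391 with an estimated correlation. Of 24 ERK feedback and immediate-early genes 9 fell (9 lower and 1 higher adjusted over the list alone; median -0.17), FOSL1, an AP-1 subunit, by -1.33 ± 0.12 and EREG, a ligand of the EGF receptor, by -1.06 ± 0.08. That list had an adjusted p of 0.00487 and an adjusted p of 0.0543 with an estimated correlation. Histone genes H2BC5 at 1.82 ± 0.15, H2BC21 at 1.74 ± 0.14 and H4C15 at 1.52 ± 0.19 were among the 8 largest rises, in a library type that captures poly(A) tails, which most histone transcripts of S phase lack. Among markers of other cell types LYZ changed by 0.64 ± 0.07, APOH by 0.32 ± 0.06 and CD68 by -0.82 ± 0.18. LY294002 changed 6565 genes, 3129 higher and 3436 lower, of which 394 changed at least 2-fold. Leaving out 1 library gave 5373 to 6418.

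Set against each other, wortmannin and LY294002 differed in single interferon-stimulated, replication and metabolic genes, which were not tested as lists here. OAS2 was higher by a log2 difference of 2.29 ± 0.22 (SE, n = 3 each, adjusted p = 1.65e-11) and IFIT1, an antiviral RNA-binding protein, by 1.42 ± 0.11 (adjusted p = 2.23e-14). MCM10, a replication factor, differed by 0.75 ± 0.04 and AKR1C2, a ketosteroid reductase, by 1.48 ± 0.12. Lower with wortmannin than with LY294002 were DPYSL3 at -1.87 ± 0.13 and TXNIP at -0.78 ± 0.07. The direct test found 3718 genes, 2126 higher and 1592 lower, 2643 to 3758 with 1 library left out and 1377 in a fit of the 6 libraries alone. Against the shared vehicle 759 genes rose with both inhibitors, 1076 fell with both and 43 went opposite ways. Because the vehicle libraries are shared, changes correlate even without any common effect. Across genes, which are not independent replicates, Pearson's r was 0.529 and 0.502 on average in 20 simulations where only the vehicle was shared, Spearman's rho was 0.619 against 0.446 and the covariance was 0.119 against 0.05555. In those simulations, which hold no effect of treatment, 0.05 genes on average rose with both and 0 fell with both. Independent lists of these sizes would share 195.9 higher and 256.2 lower genes, a value that leaves out the shared vehicle, from which part of the excess may come.

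**Figure D1:**
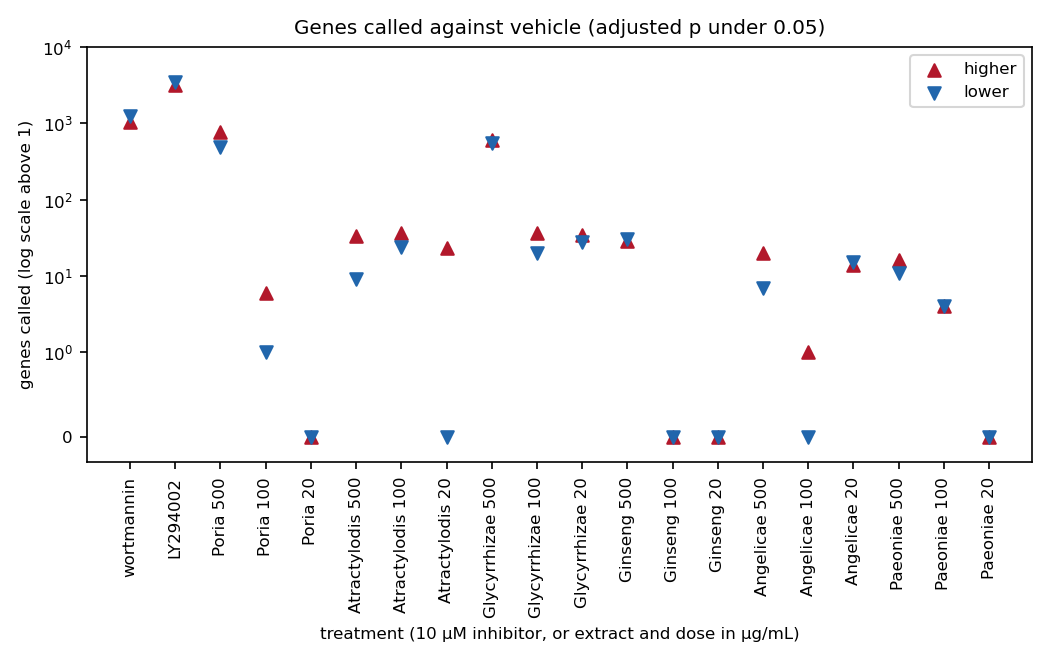
Number of genes called higher (triangles up) and lower (triangles down) at an adjusted p under 0.05 for each treatment against vehicle, on an axis that is logarithmic above 1. LY294002 changed 6565 genes, wortmannin 2300, Poria at 500 µg/mL 1256 and Glycyrrhizae at 500 µg/mL 1158, and the other 4 extracts at most 61 at any dose.

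Poria at 500 µg/mL raised the NRF2 antioxidant response, the gene set through which cells detoxify electrophiles. AKR1B10, a reductase of reactive aldehydes (chromosome 7, 134527592 to 134541408), rose from 96.6 ± 5.16 CPM in vehicle to 260.3 ± 13.8 CPM (SD, n = 3 each), a log2 fold change of 1.43 ± 0.05 (SE, adjusted p = 1.7e-25). AKR1C2 (chromosome 10, 4987400 to 5018031) rose by 1.70 ± 0.11 on the log2 scale (adjusted p = 1.71e-16) and ALDH3A1, an aldehyde dehydrogenase (chromosome 17, 19737984 to 19748943), by 1.03 ± 0.06 (adjusted p = 4.53e-19). ALDH3A1 is not a member of the NRF2 list tested here. REG4, a lectin secreted by goblet and endocrine cells (chromosome 1, 119794018 to 119811660), fell from 35.8 ± 2.60 to 22.4 ± 1.79 CPM, a log2 fold change of -0.67 ± 0.07 (adjusted p = 3.07e-09). CD200, a surface protein that restrains myeloid cells (chromosome 3, 112332347 to 112362812), fell from 9.03 ± 0.153 to 4.83 ± 1.10 CPM, a log2 fold change of -0.91 ± 0.10 (adjusted p = 2.14e-08).

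All 25 members of the NRF2 list rose with Poria at 500 µg/mL (25 adjusted over the list alone), with a median log2 fold change of 0.64 and a list adjusted p of 2.03e-62. NQO1, a quinone reductase (chromosome 16, 69706996 to 69726951), changed by 0.63 ± 0.05, ME1, a source of NADPH, by 0.61 ± 0.04, SLC7A11, the cystine importer, by 0.81 ± 0.09 and HMOX1, which breaks down haem, by 0.78 ± 0.11. AKR1C1, AKR1C2 and AKR1C3 are similar paralogs among which the quantification divides shared reads. Genes of DNA replication rose in 16 of 28 cases (21 adjusted over the list alone; median 0.18; list adjusted p = 3.22e-18), genes of mitosis in 10 of 28 (13; 0.14; 4.54e-10) and genes of ribosome biogenesis in 11 of 25 (16; 0.15; 7.23e-12). Of 18 heat shock genes 8 rose and 1 fell (13 and 1 adjusted over the list alone; list adjusted p = 1.99e-08), HSP90AA1 by 0.25 ± 0.03. Goblet and secretory cell genes fell in 6 of 16 cases (9 adjusted over the list alone; median -0.33; list adjusted p = 1.51e-07), CREB3L1, a transcription factor of secretory cells, by -0.58 ± 0.06 and FCGBP, a mucus protein, by -0.59 ± 0.13. FOXO targets fell in 7 of 24 cases (8 adjusted over the list alone; median -0.20; list adjusted p = 6.42e-07), TXNIP by -0.53 ± 0.07 and KLHL24 by -0.54 ± 0.11. BTG2, an antiproliferative factor, and TP53INP1 fell by -0.63 ± 0.08 and -0.89 ± 0.13. Both are p53 targets, but as single members of the 20 tested they are no result for that list. Of 13 mitochondrially encoded genes 9 fell (12 adjusted over the list alone), with a median of -0.45, and the list had an adjusted p of 8.73e-08 and an adjusted p of 0.121 with an estimated correlation. Mitochondrial genes took 7.77 ± 0.446% of the counts here against 8.61%, 9.90% and 11.4% in vehicle replicates 1, 2 and 3.

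Chemokines rose unevenly with Poria at 500 µg/mL: 7 of 21 members of the NF-kB and chemokine list rose (14 adjusted over the list alone), with a list adjusted p of 1.5e-06 and an adjusted p of 0.187 with an estimated correlation. CXCL1, a neutrophil attractant (chromosome 4, 73869393 to 73871242), averaged 19.7 ± 25.4 CPM against 1.92 ± 0.338 in vehicle, a log2 fold change of 3.40 ± 0.64 (SE, adjusted p = 0.000359). CXCL8, which is interleukin 8 (chromosome 4, 73740506 to 73743716), averaged 23.4 ± 21.2 against 6.26 ± 0.352 CPM, a log2 fold change of 1.93 ± 0.39 (adjusted p = 0.00085). Without Poria 500 replicate 1 the log2 fold changes were 1.39 for CXCL1, 0.84 for CXCL8 and 0.71 for CXCL3, and that of CCL20, Poria 500 vs vehicle, was 2.07 in place of 5.12, none of them called. PI3, a protease inhibitor of mucosal surfaces (chromosome 20, 45174876 to 45176544), rose from 6.43 ± 0.15 to 14.6 ± 7.44 CPM (adjusted p = 3.73e-05), and its log2 fold change was 0.70 without that library, still called.

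Poria at 500 µg/mL changed 1256 genes, 771 higher and 485 lower, of which 64 changed at least 2-fold. The count was 754 without vehicle replicate 2, 545 without vehicle replicate 3 and 777 without Poria 500 replicate 1, 960 to 1233 without any other library, and 239 in a fit of the 6 libraries alone. MUC2, the goblet mucin, fell by -0.49 ± 0.13 and lost its call without vehicle replicate 3 (-0.33) or Poria 500 replicate 2 (-0.44). Poria changed 7 genes at 100 µg/mL, 6 higher and 1 lower. NQO1 rose by 0.27 ± 0.05 on the log2 scale (n = 3, adjusted p = 0.02) and lost its call without vehicle replicate 2 (0.28) or 3 (0.21) or Poria 100 replicate 1 (0.23) or 2 (0.27). The count at 100 µg/mL was 2 without vehicle replicate 2, 3 without vehicle replicate 3, 2 without Poria 100 replicate 1, 3 without replicate 2 and 4 without replicate 3. With Poria edgeR called 0 genes at 20 µg/mL (834 at an unadjusted p under 0.05, 1 by DESeq2), and 1 without vehicle replicate 1 or without Poria 20 replicate 3.

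Within the Poria libraries, 500 against 20 µg/mL compared doses of the same code set, and the NRF2 response again rose with dose. AKR1B10 rose from 117 ± 6.28 CPM at 20 µg/mL to 260.3 ± 13.8 CPM at 500 µg/mL (SD, n = 3 each), a log2 fold change of 1.16 ± 0.05 (SE, adjusted p = 8.44e-22), with 140 ± 9.72 CPM at 100 µg/mL. ALDH3A1, which is outside the NRF2 list, rose from 33.7 ± 1.35 to 58.5 ± 3.40 CPM (0.80 ± 0.05, adjusted p = 3.33e-15). REG4 fell from 33.5 ± 2.03 to 22.4 ± 1.79 CPM (-0.58 ± 0.07, adjusted p = 1.96e-07) and CD200 from 8.61 ± 0.541 to 4.83 ± 1.10 CPM (-0.84 ± 0.10, adjusted p = 1.96e-07). Of 25 NRF2 genes 24 rose (25 adjusted over the list alone; median 0.54; list adjusted p = 2.18e-55). Genes of fatty acid synthesis rose in 7 of 12 cases (8 adjusted over the list alone; list adjusted p = 8.87e-09), SCD, a desaturase of fatty acids, by 0.33 ± 0.05. DNA replication genes rose in 12 of 28 cases (22 adjusted over the list alone; median 0.17; list adjusted p = 1.47e-19), RRM1 by 0.24 ± 0.03. Goblet genes fell in 5 of 16 cases (9 adjusted over the list alone; median -0.27; list adjusted p = 3.61e-08) and FOXO targets in 6 of 24 (9; -0.21; 3.34e-08). The NF-kB and chemokine list, with 6 of 21 members higher (8 adjusted over the list alone), had an adjusted p of 0.00227 and an adjusted p of 0.489 with an estimated correlation. CXCL8 was at 23.4 ± 21.2 against 10.4 ± 7.71 CPM (adjusted p = 0.0365). For CXCL8, Poria 500 vs 20, the log2 fold change was 0.11 without Poria 500 replicate 1, 0.93 without Poria 20 replicate 2 and 0.91 without replicate 3, not called in any of these, and 1.99 without Poria 20 replicate 1, still called. Among libraries of the same number CXCL8 was at 48.0, 11.1 and 11.2 CPM at 500 µg/mL against 19.3, 6.39 and 5.53 CPM at 20 µg/mL, higher in all 3. In all 924 genes differed, 539 higher and 385 lower. The count was 472 without Poria 20 replicate 2, 565 without Poria 20 replicate 3, 634 to 807 without any other library, and 193 in a fit of the 6 libraries alone.

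**Figure D2:**
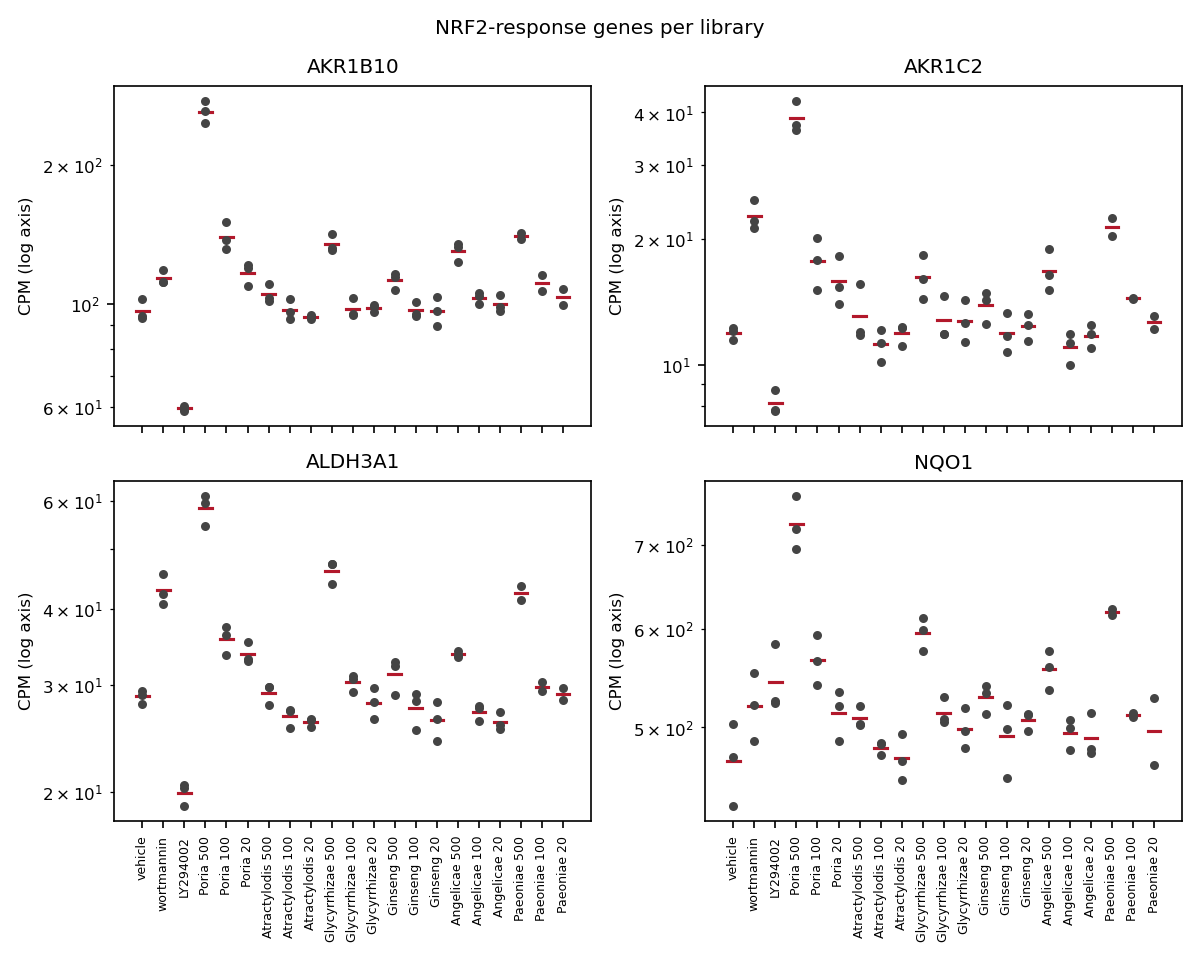
Levels of AKR1B10, AKR1C2, ALDH3A1 and NQO1 in CPM on a log axis for each group (doses in µg/mL), where points are single libraries and lines are group means. ALDH3A1 is not a member of the NRF2 list. AKR1B10 was 96.6 ± 5.16 CPM in vehicle and 260.3 ± 13.8 CPM with Poria at 500 µg/mL (SD, n = 3).

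Atractylodis raised the neutrophil-attracting chemokines CXCL1 and CXCL8 and the protease inhibitor PI3 at all 3 doses and changed few other genes. CXCL1 rose from 1.92 ± 0.338 CPM in vehicle to 35.3 ± 0.722, 36.2 ± 1.70 and 32.1 ± 6.46 CPM at 500, 100 and 20 µg/mL (SD, n = 3 each), log2 fold changes of 4.20 ± 0.62, 4.23 ± 0.62 and 4.06 ± 0.62 (SE; adjusted p = 0.000103 at 20 µg/mL). CXCL8 rose from 6.26 ± 0.352 to 32.5 ± 1.05, 32.9 ± 1.46 and 28.8 ± 3.07 CPM, log2 fold changes of 2.37 ± 0.38, 2.39 ± 0.38 and 2.20 ± 0.39 (adjusted p = 0.000258, 0.000238 and 0.000979). PI3 rose from 6.43 ± 0.15 to 29.9 ± 0.788, 30.4 ± 0.633 and 28.1 ± 2.86 CPM (adjusted p = 2.3e-11, 1.71e-11 and 1.06e-10). CXCL1 and PI3 were chosen at the lower doses after their values were seen. REG4 fell by -0.34 ± 0.07 at 500 µg/mL.

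The NF-kB and chemokine list had 9 of 21 members higher at 500 µg/mL of Atractylodis (16 adjusted over the list alone), with a median log2 fold change of 0.63 and a list adjusted p of 5.14e-26. Among them were CFB, complement factor B, at 1.57 ± 0.21 and LCN2, an iron-sequestering lipocalin, at 0.49 ± 0.09. C3, the central complement protein and one of the genes chosen after values were seen (chromosome 19, 6677704 to 6730562), was at 0.0559 CPM in vehicle and 2.37 ± 0.426 CPM at 500 µg/mL. No interferon-stimulated gene was called (5 adjusted over the list alone), while the list lay higher with a median of 0.22 (list adjusted p = 2.98e-08). Goblet genes fell in 2 of 16 cases (5 adjusted over the list alone; list adjusted p = 0.000762). No mitochondrially encoded gene was called (10 lower adjusted over the list alone; median -0.35), and that list had an adjusted p of 1.67e-07 and an adjusted p of 0.131 with an estimated correlation. Mitochondrial genes took 8.12 ± 1.01% of the counts here against 8.61%, 9.90% and 11.4% in vehicle replicates 1, 2 and 3. DESeq2 gave CXCL1, CXCL8, PI3 and CFB no adjusted p at 500 µg/mL, so its fit does not call them.

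Atractylodis changed 42 genes at 500 µg/mL (33 higher and 9 lower), 61 at 100 (37 and 24) and 23 at 20 (23 and 0). At 500 µg/mL the count was 112 without vehicle replicate 1, 21 without vehicle replicate 3, 22 without Atractylodis replicate 1 and 24 without replicate 2. REG4 lost its call without vehicle replicate 3 (-0.29) or Atractylodis replicate 1 (-0.30). The count at 100 µg/mL was 147 without vehicle replicate 1, 23 without vehicle replicate 3, 34 without Atractylodis replicate 1, 28 without replicate 2 and 39 without replicate 3, and at 20 µg/mL it was 35 without Atractylodis replicate 1. For Atractylodis edgeR found 0 genes between 500 and 20 µg/mL (857 at an unadjusted p under 0.05, 0 by DESeq2). The chemokines CXCL8 at 0.17 ± 0.32 (adjusted p = 1) and the 9 list members called at 20 µg/mL, with a median of 0.17, moved little between these doses. DNA replication genes lay higher at 500 than at 20 µg/mL with a median of 0.07, no member called (2 adjusted over the list alone) and a list adjusted p of 2.52e-09.

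**Figure D3:**
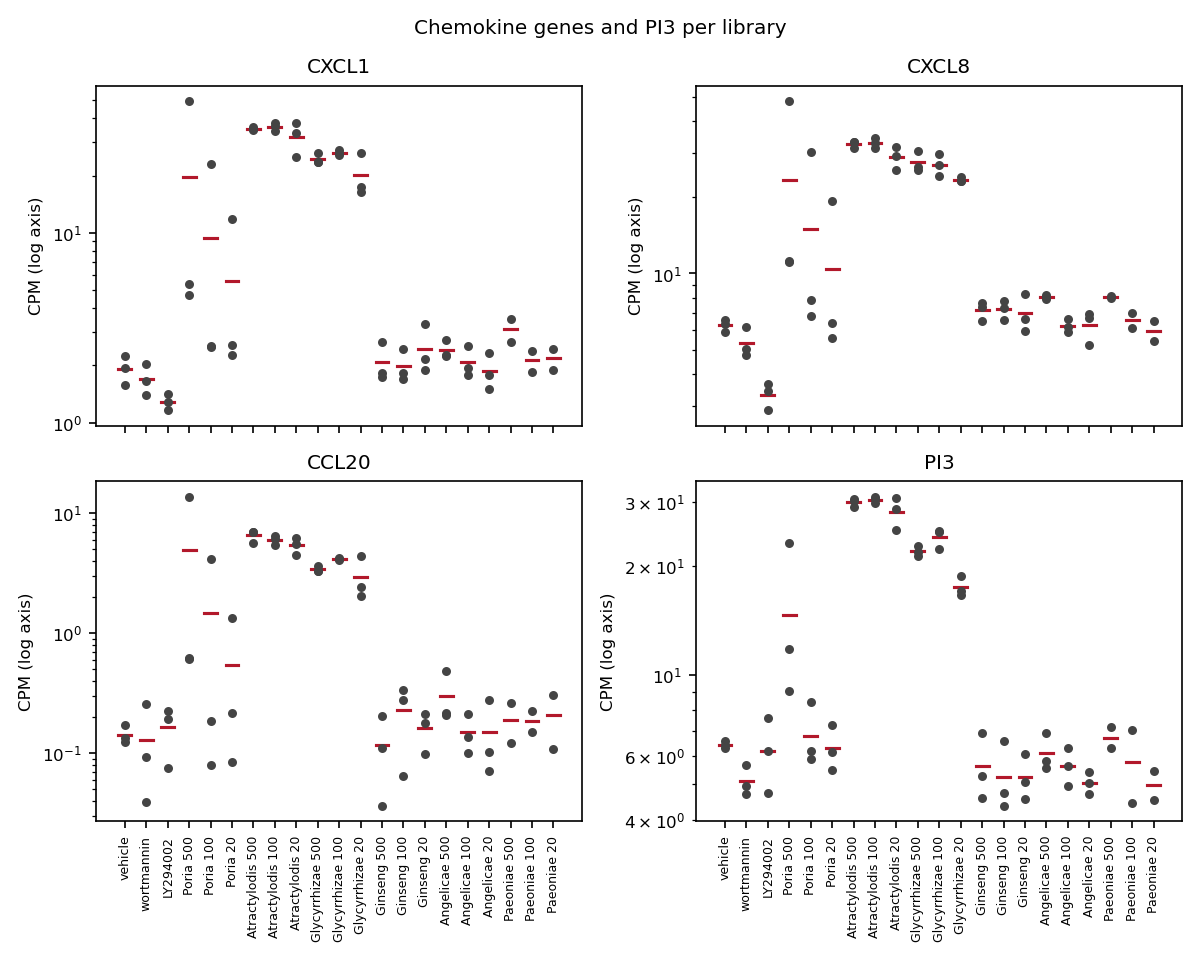
Levels of CXCL1, CXCL8, CCL20 and PI3 in CPM on a log axis for each group (doses in µg/mL), where points are single libraries and lines are group means. With Atractylodis CXCL8 was 28.8 ± 3.07 to 32.9 ± 1.46 CPM at all 3 doses against 6.26 ± 0.352 CPM in vehicle (SD, n = 3).

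Glycyrrhizae at 500 µg/mL raised chemokines and NRF2 genes and lowered goblet cell genes. CXCL8 rose from 6.26 ± 0.352 CPM in vehicle to 27.6 ± 2.65 CPM (SD, n = 3 each), a log2 fold change of 2.13 ± 0.39 (SE, adjusted p = 0.000228), and was at 26.9 ± 2.64 and 23.5 ± 0.57 CPM at 100 and 20 µg/mL (adjusted p = 0.00297 and 0.011). CXCL1 rose from 1.92 ± 0.338 to 24.5 ± 1.62 CPM, a log2 fold change of 3.67 ± 0.63 (adjusted p = 0.000126). ALDH3A1, which is outside the NRF2 list, rose from 28.7 ± 0.714 to 46.1 ± 2.02 CPM, a log2 fold change of 0.69 ± 0.06 (adjusted p = 3.38e-12). REG4 fell from 35.8 ± 2.60 to 18.4 ± 0.667 CPM, a log2 fold change of -0.96 ± 0.07 (adjusted p = 5.69e-13), and SLC6A20, an imino acid transporter (chromosome 3, 45755450 to 45796535), from 9.87 ± 0.394 to 5.46 ± 0.318 CPM (-0.86 ± 0.09, adjusted p = 1.48e-08).

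With Glycyrrhizae at 500 µg/mL, 12 of 21 members of the NF-kB and chemokine list rose (17 adjusted over the list alone; median log2 fold change 0.55; list adjusted p = 5.2e-15). LCN2 changed by 0.55 ± 0.09 and IL32 by 1.85 ± 0.36. NRF2 genes rose in 17 of 25 cases (19 adjusted over the list alone; median 0.24; list adjusted p = 1.21e-17), AKR1B10 by 0.48 ± 0.05 and NQO1 by 0.34 ± 0.05. Genes of mitosis rose in 21 of 28 cases (27 adjusted over the list alone; median 0.21; list adjusted p = 2.18e-23), CDC20 by 0.26 ± 0.04, and DNA replication genes in 16 of 28 (21; 0.18; 4.33e-17). Chaperones of the unfolded protein response rose in 9 of 18 cases (10 adjusted over the list alone; list adjusted p = 2.53e-09), HSP90B1 by 0.28 ± 0.04. Goblet genes fell in 10 of 16 cases (10 adjusted over the list alone; median -0.47; list adjusted p = 6.32e-10), CREB3L1 by -0.63 ± 0.06 and SPDEF, a goblet cell transcription factor, by -0.44 ± 0.09. Enterocyte genes fell in 5 of 19 cases (8 adjusted over the list alone; list adjusted p = 0.00041), VIL1, the microvillus protein villin, by -0.29 ± 0.04. Cholesterol genes fell in 4 of 24 cases (6 adjusted over the list alone), INSIG1 by -0.37 ± 0.07, with a list adjusted p of 0.00637 and an adjusted p of 0.516 with an estimated correlation, and 0.126 without the libraries numbered 2. BIRC3, an inhibitor of cell death induced by NF-kB, rose by 0.87 ± 0.24 and lost its call without vehicle replicate 3 (0.73) or Glycyrrhizae 500 replicate 1 (0.76).

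Glycyrrhizae changed 1158 genes at 500 µg/mL (612 higher and 546 lower), 57 at 100 (37 and 20) and 62 at 20 (34 and 28). The count at 500 µg/mL was 746 without vehicle replicate 2, 552 without vehicle replicate 3, 716 without Glycyrrhizae replicate 1, 793 to 1097 without any other library, and 711 in a fit of the 6 libraries alone. The count at 100 µg/mL was 142, 32 and 18 without vehicle replicates 1, 2 and 3, and 25 and 19 without Glycyrrhizae replicates 2 and 3. That at 20 µg/mL was 380, 10 and 3 without vehicle replicates 1, 2 and 3, and 29 and 7 without Glycyrrhizae replicates 2 and 3. At the lowest dose (CXCL1, Glycyrrhizae 20 vs vehicle, chosen after its values were seen) CXCL1 rose by 3.38 ± 0.64 on the log2 scale (adjusted p = 0.00738) and lost its call without vehicle replicate 2 (3.38) or 3 (3.50). CXCL8 at that dose lost its call without vehicle replicate 2 (1.92) or 3 (1.87) or Glycyrrhizae 20 replicate 3 (1.92), so that these calls ended with little change in size. The spread behind these calls is pooled over all groups, among them the uneven Poria libraries, and is not that of Glycyrrhizae alone.

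Between 500 and 20 µg/mL of Glycyrrhizae, genes of aryl hydrocarbon receptor and NRF2 signalling rose, goblet genes fell, and chemokines were not called. ALDH3A1 rose from 28.0 ± 1.63 to 46.1 ± 2.02 CPM (SD, n = 3 each), a log2 fold change of 0.72 ± 0.06 (SE, adjusted p = 9.43e-13), and AKR1B10 from 98.1 ± 1.75 to 135 ± 5.73 CPM (0.46 ± 0.05, adjusted p = 1.24e-07). CYP1A1, the best known target of the aryl hydrocarbon receptor, rose from 0.791 ± 0.121 to 2.86 ± 0.867 CPM (1.84 ± 0.39, adjusted p = 0.00311), a call DESeq2 did not make because it gave the gene no adjusted p. REG4 fell from 28.1 ± 0.759 to 18.4 ± 0.667 CPM (-0.61 ± 0.07, adjusted p = 3.43e-07), and HES6, a transcription factor of differentiation, from 12.5 ± 1.34 to 7.32 ± 1.32 CPM (-0.77 ± 0.17, adjusted p = 0.00433). The call of HES6 was lost without Glycyrrhizae 500 replicate 3 (-0.65) or Glycyrrhizae 20 replicate 3 (-0.69).

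By list, NRF2 genes rose with the Glycyrrhizae dose in 11 of 25 cases (16 adjusted over the list alone; median log2 fold change 0.23; list adjusted p = 1.43e-17) and aryl hydrocarbon receptor targets in 4 of 7 (4; 0.25; 1.02e-06). Genes of mitosis rose in 15 of 28 cases (24 adjusted over the list alone; median 0.17; list adjusted p = 5.46e-22), CCNA2 by 0.32 ± 0.05, and replication genes in 9 of 28 (12; 0.12; 2.26e-11). Goblet genes fell in 7 of 16 cases (8 adjusted over the list alone; median -0.30; list adjusted p = 6.23e-07). Interferon-stimulated genes fell in 7 of 29 cases (10 adjusted over the list alone; median -0.23), MX1 from 9.13 ± 0.402 to 5.64 ± 0.399 CPM, with a list adjusted p of 2.11e-07 and an adjusted p of 0.0798 with an estimated correlation. The vehicle level of MX1, given with wortmannin above, lay between these levels and nearer that at 500 µg/mL. CXCL8 differed by 0.23 ± 0.33 (adjusted p = 0.8). In all 645 genes differed, 307 higher and 338 lower. The count was 324 and 255 without Glycyrrhizae 500 replicates 1 and 3, 424 and 192 without Glycyrrhizae 20 replicates 2 and 3, and 398 in a fit of the 6 libraries alone. With offsets for transcript length and GC content 507 of 800 genes were higher, 63.4% against 47.6%.

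Ginseng changed few genes, and none of its calls at 500 µg/mL was firm. NFAT5, a transcription factor of osmotic stress (chromosome 16, 69565094 to 69704666), fell from 158 ± 6.30 to 125 ± 10.2 CPM at 500 µg/mL (SD, n = 3 each), a log2 fold change of -0.33 ± 0.06 (SE, adjusted p = 0.0119), and SLC6A20 fell by -0.49 ± 0.09 (adjusted p = 0.0119). Genes of the ATF4 amino acid response rose in 3 of 26 cases (11 adjusted over the list alone; median 0.16): PSPH, of serine synthesis, at 0.30 ± 0.07, CHAC1, which degrades glutathione, at 1.23 ± 0.30 and DDIT4, an inhibitor of mTOR, at 0.72 ± 0.18. That list had an adjusted p of 4.79e-06 and an adjusted p of 0.0583 with an estimated correlation, and 0.38 without the libraries numbered 1. Without Ginseng 500 replicate 1 CHAC1 was at 0.16 and DDIT4 at 0.17, neither called. Nuclear-encoded respiratory chain genes, with no member called (8 higher adjusted over the list alone; median 0.15), had an adjusted p of 1.98e-09 and an adjusted p of 0.22 with an estimated correlation. NRF2 genes had 1 of 25 called, AKR1B10 at 0.22 ± 0.05 (8 adjusted over the list alone), and an adjusted p of 3.27e-05 and an adjusted p of 0.188 with an estimated correlation.

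At 500 µg/mL of Ginseng 59 genes changed, 29 higher and 30 lower. The count was 154, 12 and 0 without vehicle replicates 1, 2 and 3 and 241, 10 and 1 without Ginseng replicates 1, 2 and 3. Every gene named lost its call without vehicle replicate 3, NFAT5 at -0.31, PSPH at 0.35, CHAC1 at 1.18, DDIT4 at 0.67 and AKR1B10 at 0.20. Without Ginseng replicate 3 NFAT5 (-0.30), PSPH (0.30), DDIT4 (0.88) and AKR1B10 (0.25) lost theirs too. Without vehicle replicate 2 PSPH (0.28), CHAC1 (1.16), DDIT4 (0.73) and AKR1B10 (0.20) did so. Losses of call also came without vehicle replicate 1 for PSPH (0.28) and DDIT4 (0.76), without Ginseng replicate 1 for PSPH (0.27) and AKR1B10 (0.20), and without replicate 2 for NFAT5 (-0.30), PSPH (0.33) and AKR1B10 (0.21). The call of SLC6A20, Ginseng 500 vs vehicle, was lost at -0.46 and -0.48 without vehicle replicates 2 and 3 and at -0.44 without Ginseng replicate 3. At 100 and 20 µg/mL edgeR called 0 genes (1773 and 2567 at an unadjusted p under 0.05, 0 and 155 by DESeq2). At 100 µg/mL it called 128 without Ginseng replicate 1, and at 20 µg/mL 3, 2 and 1 without vehicle replicates 1, 2 and 3 and 6 without Ginseng replicate 1. It called 0 genes between 500 and 20 µg/mL (672 at an unadjusted p under 0.05, 1 by DESeq2), and 1 without Ginseng 500 replicate 2 or 3. Genes of the unfolded protein response lay higher at 500 than at 20 µg/mL, with no member called (6 adjusted over the list alone; list adjusted p = 2.59e-07), as did DNA replication genes (2 adjusted over the list alone; list adjusted p = 2.89e-09).

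Angelicae at 500 µg/mL raised genes of the NRF2 response. AKR1B10 rose from 96.6 ± 5.16 CPM in vehicle to 130.3 ± 6 CPM (SD, n = 3 each), a log2 fold change of 0.43 ± 0.05 (SE, adjusted p = 3.45e-06), and was called with any 1 library left out. ME1 rose by 0.23 ± 0.04 (adjusted p = 0.00146) and AKR1C3 by 0.63 ± 0.13 (adjusted p = 0.0191), while NFAT5 fell by -0.30 ± 0.06 (adjusted p = 0.0191). ME1 lost its call without vehicle replicate 3 (0.20). AKR1C3 and NFAT5 lost theirs without vehicle replicate 2 (0.62 and -0.29) or 3 (0.56 and -0.28) and without Angelicae replicate 1 (0.54 and -0.29) or 3 (0.66 and -0.28). Of 25 NRF2 genes 6 rose (14 adjusted over the list alone; median 0.19; list adjusted p = 3.99e-13). DNA replication genes lay higher with no member called (14 adjusted over the list alone; median 0.11; list adjusted p = 3.2e-10). Angelicae at 500 and at 20 µg/mL differed in 3 genes, AKR1B10 at 0.38 ± 0.05 (adjusted p = 6.29e-05), ALDH3A1 at 0.37 ± 0.06 (adjusted p = 0.000314) and ME1 at 0.23 ± 0.04 (adjusted p = 0.000681), which was lost without Angelicae 500 replicate 2 (0.19). The NRF2 list, with 2 of 25 members called (12 adjusted over the list alone), had a median of 0.19 and an adjusted p of 2.65e-29, and the aryl hydrocarbon receptor list, with 1 of 7 (3), a median of 0.18 and an adjusted p of 3.43e-07.

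At 500 µg/mL of Angelicae 27 genes changed, 20 higher and 7 lower. The count was 125, 5 and 1 without vehicle replicates 1, 2 and 3 and 4, 17 and 4 without Angelicae replicates 1, 2 and 3. The 1 gene called at 100 µg/mL was DDX11, a helicase of sister chromatid cohesion (chromosome 12, 31073845 to 31104791; chosen after its values were seen), at 0.23 ± 0.04 (adjusted p = 0.0357). Leaving out any 1 library ended that call, with DDX11 at 0.25 without vehicle replicate 1, 0.24 without Angelicae 100 replicate 3 and 0.23 without any other. No gene was then called, except 1 other without Angelicae 100 replicate 3. Angelicae changed 29 genes at 20 µg/mL, 14 higher and 15 lower. That count was 141 without vehicle replicate 1, 0 without vehicle replicate 2 or 3, 7 without Angelicae replicate 1 and 0 without replicate 2 or 3. It was 388 in a fit of the 6 libraries alone, 443 by DESeq2 and 234 with the replicate number as a block.

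Paeoniae, with 2 libraries per dose, raised NRF2 genes at 500 µg/mL. AKR1B10 rose from 96.6 ± 5.16 CPM in vehicle (SD, n = 3) to 140.4 ± 3.22 CPM (n = 2), a log2 fold change of 0.54 ± 0.06 (SE, adjusted p = 6.07e-08). ALDH3A1, which is outside the NRF2 list, rose by 0.56 ± 0.06 on the log2 scale (adjusted p = 6.07e-08), AKR1C2 by 0.84 ± 0.12 (adjusted p = 4.45e-05) and NQO1 by 0.40 ± 0.06 (adjusted p = 4.45e-05). REG4 fell from 35.8 ± 2.60 to 25.8 ± 0.655 CPM (-0.47 ± 0.08, adjusted p = 0.00102). SELENOT, a selenoprotein of the endoplasmic reticulum (chromosome 3, 150602875 to 150630445), changed by -0.24 ± 0.05, SELENOW by -0.28 ± 0.06 and GPX1, the selenium-dependent glutathione peroxidase, by -0.25 ± 0.05. These 3 lost their calls without Paeoniae 500 replicate 2 (-0.22, -0.28 and -0.19), SELENOT also without vehicle replicate 3 (-0.23) or Paeoniae 500 replicate 1 (-0.26), SELENOW without Paeoniae 500 replicate 1 (-0.28), and SELENOW and GPX1 without vehicle replicate 1 (-0.22 each) or 2 (-0.27 and -0.25).

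Of 25 NRF2 genes 8 rose with Paeoniae at 500 µg/mL (18 adjusted over the list alone; median log2 fold change 0.29; list adjusted p = 2.13e-29). Goblet genes fell in 2 of 16 cases (3 adjusted over the list alone; median -0.20; list adjusted p = 7.98e-05). Metallothioneins, which bind zinc and copper, lay lower with no member called (5 adjusted over the list alone; median -0.47; list adjusted p = 1.37e-05). Between 500 and 20 µg/mL 6 genes differed, 4 higher and 2 lower. ALDH3A1 rose by 0.55 ± 0.07 (adjusted p = 2.3e-06), AKR1B10 by 0.44 ± 0.06 (adjusted p = 0.000147) and AKR1C2 by 0.76 ± 0.13 (adjusted p = 0.00372). Without Paeoniae 20 replicate 2 AKR1B10 (0.39) and AKR1C2 (0.71) lost their calls, AKR1C2 also without Paeoniae 500 replicate 1 (0.68) or Paeoniae 20 replicate 1 (0.81). The NRF2 list had 3 of 25 members called (14 adjusted over the list alone; median 0.24; list adjusted p = 3.16e-36) and the aryl hydrocarbon receptor list 2 of 7 (3; 0.32; 1.68e-10). Interferon-stimulated genes lay lower at 500 than at 20 µg/mL with no member called (5 adjusted over the list alone; median -0.25; list adjusted p = 6.54e-12).

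At 500 µg/mL of Paeoniae 27 genes changed, 16 higher and 11 lower, with 15 without vehicle replicate 3 and 8 without Paeoniae replicate 2. REG4 lost its call without Paeoniae replicate 2 (-0.45), whereas AKR1B10, ALDH3A1, AKR1C2 and NQO1 were called with any 1 library left out. Paeoniae changed 8 genes at 100 µg/mL, 4 each way, with 72, 1 and 1 without vehicle replicates 1, 2 and 3 and 19 and 1 without Paeoniae replicates 1 and 2. For Paeoniae at 20 µg/mL edgeR called 0 genes (1163 at an unadjusted p under 0.05, 13 by DESeq2). The count between doses was 2 without Paeoniae 500 replicate 1, and 3 and 1 without Paeoniae 20 replicates 1 and 2.

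Whether extracts of the same code set differed in the effect of dose was tested directly. Poria raised AKR1B10 more than Atractylodis did between 20 and 500 µg/mL, by a log2 difference of 0.99 ± 0.07 (SE, n = 3 per group, adjusted p = 4.13e-13), and AKR1C2 by 1.15 ± 0.16 (adjusted p = 9.13e-06). Lower for Poria were CD200 at -0.84 ± 0.14 (adjusted p = 0.000759), BTG2 at -0.62 ± 0.11 (adjusted p = 0.000759) and AQP1, a water channel, at -0.65 ± 0.15 (adjusted p = 0.0204). The difference of AQP1, Poria minus Atractylodis dose effect, lost its call without Atractylodis 20 replicate 1 (-0.67) or 3 (-0.64), Atractylodis 500 replicate 3 (-0.61), Poria 500 replicate 2 (-0.62) or Poria 20 replicate 2 (-0.61). In all 66 genes differed, 46 higher and 20 lower, with 40 without Poria 500 replicate 1, 34 without Poria 20 replicate 2, 35 without Atractylodis 20 replicate 1 and 41 without Atractylodis 500 replicate 3. Between Glycyrrhizae and Ginseng 8 genes differed, 2 higher and 6 lower for Glycyrrhizae. ALDH3A1 was higher at 0.47 ± 0.08 (adjusted p = 0.00165), and lower were REG4 at -0.62 ± 0.10 (adjusted p = 0.00114), ARSD, a lysosomal sulfatase family member, at -0.38 ± 0.08 (adjusted p = 0.0421) and RAP1GAP, which inactivates RAP1, at -0.29 ± 0.05 (adjusted p = 0.0107). RAP1GAP lost its call without Glycyrrhizae 500 replicate 1 (-0.29) or 3 (-0.26), Glycyrrhizae 20 replicate 3 (-0.29), Ginseng 20 replicate 1 (-0.26) or Ginseng 500 replicate 3 (-0.28). ARSD lost its call without any library but Glycyrrhizae 20 replicate 1, at -0.33 to -0.40. That count was 4 without Glycyrrhizae 500 replicate 1, 5 without replicate 3, 13, 5 and 4 without Glycyrrhizae 20 replicates 1, 2 and 3, 4 without Ginseng 20 replicate 1 and 4 without Ginseng 500 replicate 3. Between Angelicae and Paeoniae edgeR called 0 genes (410 at an unadjusted p under 0.05, 0 by DESeq2), and 1 without Paeoniae 500 replicate 2 or Angelicae 500 replicate 3.

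Over all comparisons against vehicle, 117 of 232 list tests passed, 75 higher and 42 lower, and 49 with an estimated correlation. Of 174 list tests of 500 against 20 µg/mL 71 passed, 53 higher and 18 lower, and 27 with an estimated correlation. The NRF2 list passed with both correlations in 4 of the 6 extracts between 500 and 20 µg/mL, with medians of 0.54 for Poria, 0.23 for Glycyrrhizae, 0.19 for Angelicae and 0.24 for Paeoniae. Across all genes tested, which are not independent replicates, the log2 changes between 20 and 500 µg/mL correlated by -0.0886 to 0.109 (Pearson's r) over the 15 pairs of extracts, with a median of 0.0211. Spearman's rho was 0.0182 to 0.274 over the same pairs, and the median of Pearson's r was 0.246 over genes with a mean of at least 10 CPM.

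**Figure D4:**
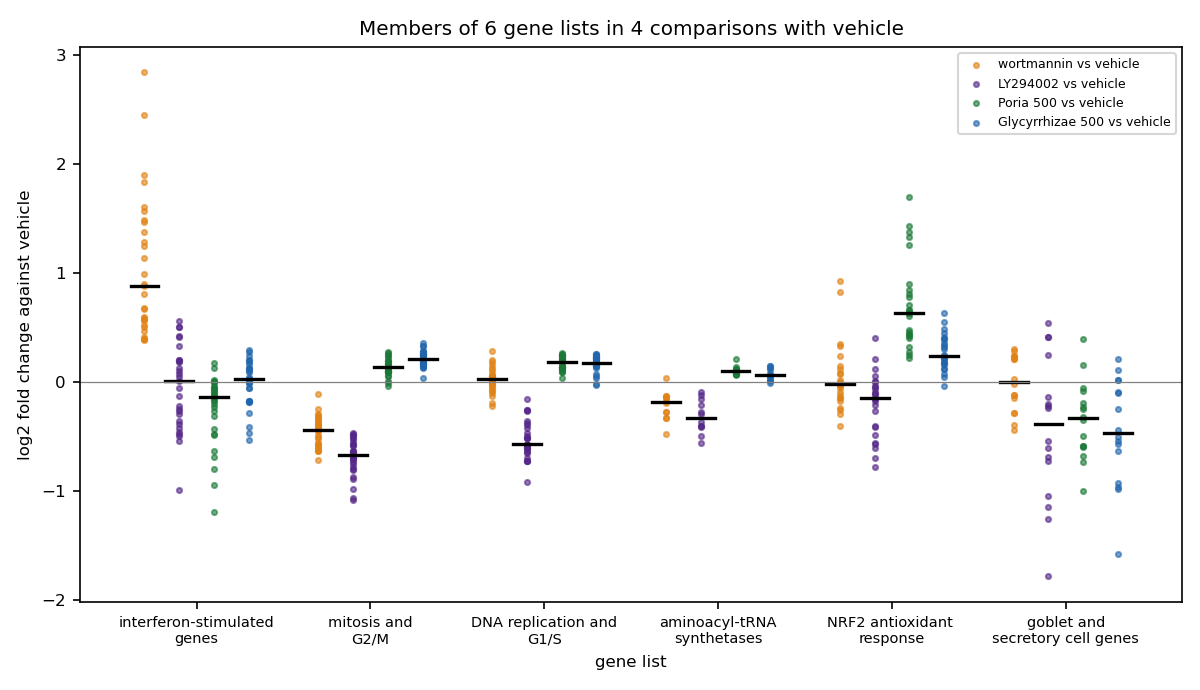
Log2 fold change against vehicle of each tested member (points) of 6 gene lists in 4 comparisons (colours), with the median of each list as a black line. The interferon list had a median of 0.89 with wortmannin, the mitosis list -0.67 with LY294002 and the NRF2 list 0.64 with Poria at 500 µg/mL.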

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

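No test in this part was chosen after its result was seen. The effect of dose (500 against 20 µg/mL) differed between Poria and Atractylodis, tested as a difference of differences, in 66 genes, among them AKR1B10 (0.99 ± 0.07, SE, n = 3 per group), AKR1C2 (1.15 ± 0.16) and CD200 (-0.84 ± 0.14). PI3, at 1.15 ± 0.25, was at 0.64 and not called without Poria 500 replicate 1. Of 100 random regroupings of the same 12 libraries, the real one included, 7 gave as many genes as the 19 of a fit of these libraries alone, and the highest other gave 210. Such regroupings also put effects of extract and of dose, which are a structure of these samples, into the contrast, so that they leave open whether chance gives the count.

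The same test between Glycyrrhizae and Ginseng found 8 genes, among them ALDH3A1 (0.47 ± 0.08) and REG4 (-0.62 ± 0.10). Here too 7 of 100 regroupings gave at least the 4 genes of a fit of these 12 libraries alone, with 1430 in the highest other, which leaves chance open for the same reason.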

How the results depend on the processing

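DESeq2 size factors left every gene count within 1.5 times the count above and no named gene turned its direction under size factors, the replicate block, offsets, no filter, DESeq2 or the compared groups alone. Named gene results numbered 1903, each a gene in a comparison. They include reference genes and genes chosen later that were not called, which had no call to lose. Size factors ended 3 calls, offsets 19, no filter 63, DESeq2 55 and the compared groups alone 308. They added 0, 26, 145, 38 and 11, and the replicate block added 35. Genes that a fit of the compared groups alone filtered out are not in its counts. For 53 of the 55 calls lost with DESeq2 it gave no adjusted p. Leaving out 1 library ended 1040 calls, added 50 and turned 5, counted over all libraries left out. A change of sign of a gene that no fit calls is not counted. Depth limits genes near 0 CPM, where 1 count was 0.0489 to 0.0282 CPM. Offsets were chosen after the data were seen, and the cause of a change was not tested unless it is named.

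Without a filter on low counts the number of genes was 746 for Atractylodis, 824 for Ginseng, 882 for Angelicae and 419 for Paeoniae against vehicle at 500 µg/mL. It was 228 for Poria, 667 for Atractylodis, 829 for Glycyrrhizae, 388 for Ginseng, 559 for Angelicae and 610 for Paeoniae at 100 µg/mL. It was 98 for Poria, 546 for Atractylodis, 1068 for Glycyrrhizae, 808 for Ginseng, 1141 for Angelicae and 213 for Paeoniae at 20 µg/mL. It was 144 for Atractylodis, 70 for Ginseng, 88 for Angelicae and 77 for Paeoniae between 500 and 20 µg/mL. It was 226 for Poria and Atractylodis, 109 for Glycyrrhizae and Ginseng and 64 for Angelicae and Paeoniae for the difference of dose effects. Here 34237 genes were tested and the estimated prior degrees of freedom were infinite, against 6.955 with the filter.

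With the replicate number as a block the count was 193 for Ginseng, 219 for Angelicae and 74 for Paeoniae against vehicle at 500 µg/mL. It was 11 for Poria, 117 for Atractylodis, 193 for Glycyrrhizae, 2 for Ginseng, 10 for Angelicae and 51 for Paeoniae at 100 µg/mL. It was 1 for Poria, 221 for Glycyrrhizae, 77 for Ginseng, 234 for Angelicae and 25 for Paeoniae at 20 µg/mL. It was 1 for Ginseng and 5 for Angelicae between 500 and 20 µg/mL. It was 105 for Poria and Atractylodis and 27 for Glycyrrhizae and Ginseng for the difference of dose effects. With DESeq2 in place of edgeR it was 113 for Atractylodis, 227 for Ginseng, 255 for Angelicae and 73 for Paeoniae against vehicle at 500 µg/mL. It was 16 for Poria, 109 for Atractylodis, 181 for Glycyrrhizae, 19 for Angelicae and 166 for Paeoniae at 100 µg/mL. It was 1 for Poria, 427 for Glycyrrhizae, 155 for Ginseng, 443 for Angelicae and 13 for Paeoniae at 20 µg/mL. It was 1 for Ginseng and 6 for Angelicae between 500 and 20 µg/mL. It was 103 for Poria and Atractylodis and 13 for Glycyrrhizae and Ginseng for the difference of dose effects.

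With offsets for transcript length and GC content the count was 58 for Angelicae and 47 for Paeoniae against vehicle at 500 µg/mL. It was 0 for Angelicae and 17 for Paeoniae at 100 µg/mL. It was 1 for Poria, 129 for Glycyrrhizae, 45 for Ginseng and 58 for Angelicae at 20 µg/mL. The share of higher genes moved from 52.9% to 63.6% for Glycyrrhizae at 500 µg/mL, from 74.1% to 56.9% for Angelicae at 500 µg/mL, from 48.3% to 37.9% for Angelicae at 20 µg/mL and from 54.8% to 45.0% for Glycyrrhizae at 20 µg/mL. Most called genes also went the other way for Angelicae at 500 µg/mL in the compared groups alone (29 higher, 34 lower), for Ginseng at 500 in the same fit (3 and 0), for Paeoniae at 500 µg/mL by DESeq2 (34 and 39) and for Glycyrrhizae 500 vs 20 by DESeq2 (408 and 345). They did so without a filter for Poria at 100 (107 and 121), Ginseng at 500 (471 and 353), Angelicae at 20 (639 and 502) and Paeoniae at 500 (200 and 219). With 1 library left out they did so for Glycyrrhizae at 500 without vehicle replicate 2 (367 and 379) and at 20 without Glycyrrhizae 20 replicate 1 (46 and 47), for Ginseng at 500 without its replicate 3 (1 and 0), for Angelicae at 20 without its replicate 1 (5 and 2), and for Glycyrrhizae 500 vs 20 without replicate 2 at 500 (261 and 258) or at 20 (233 and 191). In a fit of the compared groups alone, which has fewer libraries to estimate the spread, the count was 239 for Poria, 24 for Atractylodis, 711 for Glycyrrhizae, 3 for Ginseng and 63 for Angelicae against vehicle at 500 µg/mL. It was 1 for Poria, 28 for Atractylodis, 152 for Glycyrrhizae and 0 for Angelicae at 100 µg/mL. It was 27 for Glycyrrhizae, 6 for Ginseng, 388 for Angelicae and 4 for Paeoniae at 20 µg/mL. It was 193 for Poria, 398 for Glycyrrhizae, 1 for Angelicae and 10 for Paeoniae between 500 and 20 µg/mL. It was 19 for Poria and Atractylodis and 4 for Glycyrrhizae and Ginseng for the difference of dose effects. It was 1249 for wortmannin and 1377 for wortmannin against LY294002.

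With 1 library left out, which leaves fewer samples, the count ranged from 545 to 1233 for Poria, 21 to 112 for Atractylodis, 552 to 1097 for Glycyrrhizae, 0 to 241 for Ginseng, 1 to 125 for Angelicae and 8 to 33 for Paeoniae against vehicle at 500 µg/mL. It ranged from 2 to 8 for Poria, 23 to 147 for Atractylodis, 18 to 142 for Glycyrrhizae, 0 to 128 for Ginseng, 0 to 1 for Angelicae and 1 to 72 for Paeoniae at 100 µg/mL. It ranged from 0 to 1 for Poria, 16 to 35 for Atractylodis, 3 to 380 for Glycyrrhizae, 0 to 6 for Ginseng and 0 to 141 for Angelicae at 20 µg/mL. It ranged from 472 to 807 for Poria, 192 to 578 for Glycyrrhizae, 0 to 1 for Ginseng and 1 to 4 for Paeoniae between 500 and 20 µg/mL. It ranged from 34 to 62 for Poria and Atractylodis, 4 to 13 for Glycyrrhizae and Ginseng and 0 to 1 for Angelicae and Paeoniae for the difference of dose effects. Where this leaves 1 Paeoniae library, it is assumed to vary like the other groups.

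Gene lists passed in 117 and 71 tests, and in 49 and 27 with an estimated correlation, in 130 and 73 without a filter, in 122 and 74 with the block, and in 104 to 118 and 60 to 76 without all libraries of 1 replicate number. The median correlation of dose effects over the 15 pairs of extracts was 0.0211, 0.00466 without a filter, 0.246 over genes with a mean of at least 10 CPM, and 0.00301 to 0.0171 without those of 1 number. Without vehicle replicate 1 the log2 fold change turned to 0.0308 for CYP1A1, wortmannin vs vehicle, with a range of -1.93 to 0.0308 over libraries left out, and to 0.29 for CYP1A1, LY294002 vs vehicle, with a range of -1.67 to 0.29. Between 500 and 20 µg/mL of Poria, CXCL1 ranged from -0.12 to 3.05, CXCL6 from -0.17 to 2.28 and CXCL3 from -0.30 to 2.00, the lowest in each case without Poria 500 replicate 1. Poria 20 replicate 1, high as well, then stays in the reference. Among libraries of the same number CXCL1 and CXCL3 were higher at 500 in 3 of 3 and CXCL6 in 2 of 3. Lists that turned direction without replicate 1 had an adjusted p of 0.0095 for FOXO targets, Ginseng 500 vs 20 (range 7.59e-05 to 0.0739), 0.153 for ATF4 amino acid response, Ginseng 500 vs 20 (4.47e-09 to 0.153) and 0.963 for mitochondrially encoded genes, Ginseng 500 vs 20 (0.000269 to 0.963). Without replicate 2 it was 0.74 for nuclear-encoded respiratory chain, Paeoniae 500 vs 20 (1.32e-05 to 0.74) and 0.000987 for mitochondrially encoded genes, Paeoniae 500 vs 20 (4.87e-05 to 0.93). These results rest on fewer samples.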

Other observations

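All tests in this part were chosen after the results were seen, except the test of the vehicle libraries on genes called in several extracts and the regroupings of libraries. Compared directly at 20 µg/mL, within code sets, Atractylodis differed from Poria in 28 genes (22 higher and 6 lower, 1321 at an unadjusted p under 0.05) and Glycyrrhizae from Ginseng in 14 (14 and 0, 566). In each comparison 5 members of the NF-kB and chemokine list were among the genes called higher. Over the 9 members of that list called with Atractylodis at 20 µg/mL, which are CXCL1, CXCL2, CXCL3, CXCL8, CCL20, IL32, LCN2, CFB and SAA1, the median log2 fold changes against vehicle at 500, 100 and 20 µg/mL were 2.79, 2.74 and 2.51 with Atractylodis and 2.30, 2.36 and 1.95 with Glycyrrhizae. With Poria they were 2.14, 1.39 and 0.75, and 1.93, 1.31 and 0.80 with SAA1, which had no count in vehicle, at its lower bound from 3 counts over the vehicle group. The other medians of Atractylodis and Glycyrrhizae were the same with SAA1 at its bound. The Poria medians rested on the libraries numbered 1: as differences of mean log2 CPM they were 1.342, 0.8997 and 0.5717 with all libraries and 0.6716, 0.2215 and 0 without these, against 2.171 to 1.797 with Glycyrrhizae and 2.646 to 2.204 with Atractylodis without theirs. At 500 µg/mL they were 0.16 with Ginseng, 0.33 with Angelicae and 0.43 with Paeoniae, where none of the 9 was called. CXCL1, CXCL2 and CXCL3 are similar paralogs that share reads.

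A set of 68 genes was called in the same direction with at least 3 extracts at 500 µg/mL, 50 higher and 18 lower. DDX11 was higher and PLEKHA6 lower with 6 extracts. Of the 68, 66 were called with Poria and 66 with Glycyrrhizae, against 29 with Atractylodis, 27 with Ginseng, 23 with Angelicae and 21 with Paeoniae. Signed by that direction, their median log2 fold change over the extracts was 0.240 at 500 µg/mL and 0.159 at 20 µg/mL. Genes and signs were taken from the calls at 500 µg/mL, so the sign of the first value was fixed in advance. The second uses the same vehicle libraries, which favours the same sign.

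The chemokine rise with Atractylodis and Glycyrrhizae was about as large at 20 as at 500 µg/mL. A difference between code sets as its whole cause would show in the other extract of each set, but the larger median there at 20 µg/mL was 0.747, in Poria, against 1.95 in Glycyrrhizae. RNA from leukocytes is argued against too, since PTPRC, TYROBP, CD3E and CSF1R together reached 0.283% of the CXCL8 level in these libraries. A response that is largely complete at the lowest dose is a candidate explanation, since the members moved by at most 0.214 (median) between 20 and 500 µg/mL in either extract. That value leaned on the libraries numbered 1: by number, the medians were -0.04575, 0.2869 and 0.325 with Atractylodis and -0.1575, 0.1818 and 0.4015 with Glycyrrhizae, so that a further rise with dose is not excluded. The members were also chosen by their call with Atractylodis at 20 µg/mL. For that extract this favours high values at 20 µg/mL, a small rise to 500 and a large difference from Poria. A substance that does not scale with the nominal dose was not tested.

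For the 68 genes called with several extracts, chance values of the shared vehicle libraries would move both inhibitor groups the same way. The larger signed median of these was 0.00780, with wortmannin, and the other was -0.0985, with LY294002. Both lay far below the 0.240 of the extracts, which the prediction written beforehand took as a sign against this explanation. Of the genes, 38 kept their sign with wortmannin and 22 with LY294002. The SD over the genes with wortmannin was 0.525, a spread of single genes and not the error of their median. By that prediction chance values of vehicle are argued against as the whole cause. The inhibitors change many genes themselves, so such values are not excluded. Trends with transcript length and GC content as the whole cause are argued against, since the signed median was 0.235 with offsets for them. Over the set as a whole, a difference between code sets cannot be told apart from an effect of the extracts. The signed median between 20 and 500 µg/mL was 0.0747, part of the 0.240, and vehicle belongs to a code set of its own. Single members differed in this. Between these doses, within code sets, AKR1B10 and ALDH3A1 rose with Poria, Glycyrrhizae, Angelicae and Paeoniae, and REG4 fell with Poria and Glycyrrhizae. Chemokines were not called between these doses with Atractylodis or Glycyrrhizae.

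In Poria 500 replicate 1 CXCL8 was at 48.0 CPM against 11.1 and 11.2 CPM in the other libraries of its group, and CXCL1 at 49.1 against 5.39 and 4.71 CPM. A swap with an Atractylodis library is argued against, since its AKR1B10 level was 273.7 CPM and at most 110.6 CPM in any Atractylodis library. An event in this library alone is argued against as well: in replicate 1 of Poria 100 and Poria 20 the median of the 9 genes also lay above the other replicates, by at least 1.271 on the log2 scale, with medians of 1.75 and 1.27 against 2.10 at 500 µg/mL. Replicate 1 was the highest for 9 of 9 genes at 100 µg/mL, 6 at 20 and 7 at 500. A weaker rise in every Poria 500 library may be present, since the lower of the other libraries had 11.09 CPM of CXCL8 against 5.88 to 6.57 CPM in vehicle. Replicate 1 was also the highest for 8 of 9 genes with Atractylodis and with Glycyrrhizae at 20 µg/mL, by smaller medians of 0.349 and 0.232, but for at most 3 of 9 at their higher doses. What these libraries numbered 1 share stays open and was not tested.

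Since SELENOT, SELENOW and GPX1 were lower with Paeoniae at 500 µg/mL, a lower level of selenoprotein transcripts as a class was tested as a hypothesis on 13 selenoprotein genes not seen before. SELENOH had also been seen and was left out with them. The 13 genes lay higher rather than lower against 20 µg/mL (camera with an estimated correlation, p = 0.356) and against vehicle (p = 0.486). The test thus gave no sign of a lower level of these 13 genes. It does not cover the genes left out, so it cannot speak for the whole class.

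Lists were tested again after random regroupings of the libraries, 100 per family with the real one included. Of these, 1 of 100, the real grouping itself, gave as many list calls as the 117 against vehicle (highest other 106, median 58). The same held for the 71 between doses (highest other 70, median 48). A share of 1 of 100 is the smallest that such a test can give. The regroupings also hold real effects of treatment, so they leave open how many calls chance alone would give. With an estimated correlation the regroupings gave medians of 0 and 0 calls and at most 0 and 1, against 49 and 27.

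For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. In fits of the 6 libraries alone the real split and the highest other gave 1249 and 2 genes for wortmannin, 4555 and 0 for LY294002, and 1377 and 1 for wortmannin against LY294002. At 500 µg/mL they gave 239 and 2 for Poria, 24 and 4 for Atractylodis, 711 and 4 for Glycyrrhizae, 3 and 2 for Ginseng, and 63 and 3 for Angelicae. At 100 µg/mL they gave 1 and 5 for Poria (4 of 10 splits as large), 28 and 4 for Atractylodis, 152 and 1 for Glycyrrhizae, 0 and 882 for Ginseng and 0 and 2 for Angelicae. At 20 µg/mL they gave 0 and 115 for Poria, 34 and 7 for Atractylodis, 27 and 1 for Glycyrrhizae, 6 and 2 for Ginseng and 388 and 0 for Angelicae. Between 500 and 20 µg/mL they gave 193 and 1 for Poria, 0 and 7 for Atractylodis, 398 and 1 for Glycyrrhizae, 0 and 1 for Ginseng and 1 and 108 for Angelicae (6 of 10 as large). Where the real count was 0 all 10 splits were as large. The 882 genes arose with Ginseng 100 replicate 1 grouped with vehicle replicates 2 and 3, which points to a structure of these samples, as do the 115 and the 108. Mitochondrial genes took 10.1%, 9.90% and 11.4% of the counts in these 3 libraries against 8.61% in vehicle replicate 1 and 7.86% and 7.51% in Ginseng 100 replicates 2 and 3. Their scores on the second principal component were 17.97, 14.56 and 24.29 against 6.09, -5.62 and -8.82. Vehicle replicate 3 had the highest share and the highest score of all 60 libraries.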
